A study of Mus musculus with 8 samples.

How the data were processed

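Hearts were dissected from male and female C57BL/6 mice aged 8 weeks, RNA was extracted with Trizol and libraries were made from 1 µg of total RNA with the Illumina TruSeq RNA Sample Prep Kit, per the labels' protocols. The 8 libraries form 2 groups, 4 female and 4 male. The labels state neither that each library came from a separate animal nor which part of the heart was used, and give no batch or date.

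The authors deposited a table of raw counts for 49315 genes, made with Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 on GRCm38 (mm10), which the submitters' processing notes name without their order. The annotation version, the strand setting and the treatment of reads that map to several places are not stated. Reads of overlapping genes on opposite strands therefore cannot be told apart, and genes with near-identical copies are uncertain, among them Ifi205, the hemoglobin, Mup and Serpina genes, the actins and part of the mitochondrial genes. The 8 deposited tables of single samples held 100% the same counts, with the exon coordinates and summed exon length of each gene. The authors also deposited a normalized table, a signal that equals the raw count divided by 1 size factor per library (0.863 to 1.196), as found from the values. It holds the 16160 genes with more than 80 counts over the 8 libraries, and 100% of its values came out whole within 0.01 when multiplied back. Of the IDs, 48970 matched a symbol, and 18774 genes had no count in any library. Coordinates are those of the deposited tables.

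Total counts lay between 32746054 and 47097765, so 1 count was worth 0.0212 to 0.0305 CPM. The totals of the male libraries all exceeded those of the female ones (exact two-sided permutation test, p = 0.029, the smallest that 4 against 4 allows). A floor of 3 counts over a group of 4 was used where a group had 0 counts, and intervals and floors cover counting error only.

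Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which kept 16180, scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, male minus female, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.081. CPM used the scaled library sizes, and log2 CPM a prior count of 2. Genes were also counted apart for autosomes and the X chromosome. The count of X-linked genes was set against autosomes with Fisher's exact test.

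Gene lists were fixed from general knowledge before the data were examined: 44 lists with 704 genes, 3 of which had no match. They comprise Y-linked genes, genes that escape X inactivation and Xist, which were reported gene by gene, and pathway and cell type lists, of which 41 had at least 5 tested members. A list of lung markers had 3 tested members and was not tested. The 41 lists cover energy metabolism, contraction, hormone response, stress and immunity, and markers of cell types that a heart sample can hold. They were tested on log2 CPM with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, then with a correlation estimated for each list and with fry. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes.

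The genes named in the text follow a rule also fixed before the data were examined. It takes the tested Y-linked and escape genes and Xist, and the 12 autosomal genes with the largest fold change in each direction among those called, without overlap between the sexes, with a mean log2 CPM of at least 1 and with a symbol that is not a clone name. It adds the 5 other X-linked genes called with the smallest p and a mean log2 CPM of at least 1. For each list it takes up to 2 called members in each direction with the smallest p, or the member with the smallest p where none was called. This gave 110 genes, of which 4 are not reported here, and a gene named outside the rule is said to be so.

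The alternatives fixed before the data were examined were DESeq2 size factors and upper quartile scaling, no filter, a filter of 1 CPM in 4 libraries, the Wald test of DESeq2 1.42.0 and limma-voom. They also comprised the replicate number as a block, each library left out in turn, limma on log2 of the deposited normalized signal plus 1, changes of at least 1.5-fold, and list tests without sex-linked genes. Chosen after the data were seen were thinning of all libraries to the smallest total, removal of mitochondrial genes and a covariate made of the white adipocyte markers. The 35 splits of the 8 libraries into 4 and 4 were also fitted.

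The procedure was tested on simulated data, with counts for 16180 genes drawn from the means and library sizes of these samples. Of 50 genes each changed by 1.25, 1.5, 2 and 4-fold, 46%, 58%, 86% and 98% were recovered for male minus female, with 9 false calls among 153 (5.9%). With no gene changed, 0 were called by edgeR. Counts were drawn gene by gene, without correlation between the members of a list, so false calls of lists were not measured by this simulation. Fold changes had a Spearman correlation across genes of -0.01 with GC content, known for 99.76% of the genes tested, and of -0.09 with exon length; genes are not independent replicates.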

Results

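RNA sequencing measured gene expression in 8 libraries from hearts of C57BL/6 mice aged 8 weeks, 4 from females and 4 from males. C57BL/6 is a standard inbred laboratory strain, so the mice share nearly the same genome apart from the sex chromosomes. The series was made to compare the transcriptomes of male and female adult hearts, and that contrast is the one reported here. Total counts per library ran from 32746054 to 35467832 in females and from 39612848 to 47097765 in males, so depth and sex moved together. The labels do not state that each library came from a separate animal, and p-values then measure the spread between these samples. Expression is given as CPM, counts scaled to library size, as mean ± SD over the 4 libraries of a sex, and log2 fold changes are male minus female with their standard error (SE). The SE is the absolute log2 fold change divided by the square root of F from the quasi-likelihood test.

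The hearts of the sexes were told apart by their sex chromosomes and by a broad set of small autosomal differences. Of 16180 genes tested, 613 differed between the sexes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 329 higher in males and 284 higher in females. Of 15630 autosomal genes tested, 571 differed, 305 higher in males and 266 higher in females. The rest were 22 X-linked genes of 507, 5 of 6 genes annotated on the Y chromosome, 14 mitochondrially encoded genes of 32 and 1 gene on an unplaced scaffold. Most autosomal differences were modest, with a median of 1.3-fold and an interquartile range of 1.19 to 1.56. In 597 of the 613 genes the 4 male and 4 female values did not overlap, which largely follows from their choice by a small p. The same was true of 1949 of all 16180 genes tested, where chance gives 2.86% for 4 against 4. The first principal component held 36.1% of the variance and separated the sexes. Females lay between -23.3 and -14.3 on it and males between 14.7 and 21.7. The count of genes fell to 315, 354 and 379 without male replicate 3, female replicate 2 and female replicate 3. It was 959 in the DESeq2 test and 182 when a change of at least 1.5-fold was also asked for. With the mean of the white adipocyte markers as a covariate, a measure that separated the sexes by itself, 6 genes were called, 5 of them among the 613.

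**Figure D1:**
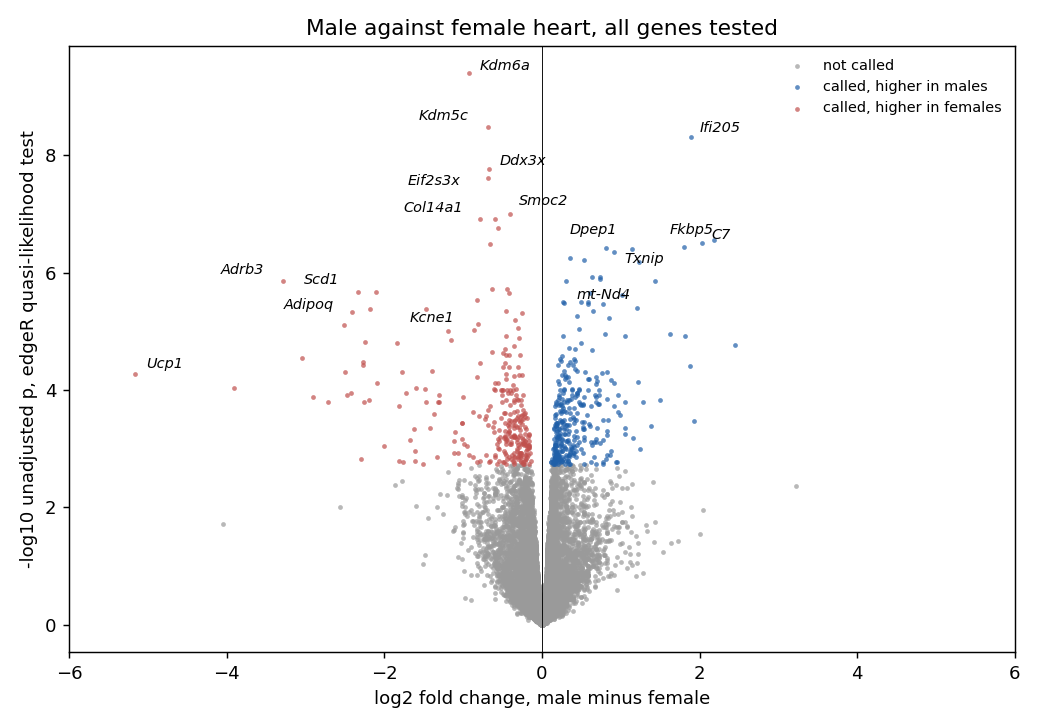
Log2 fold change (male minus female, horizontal axis) against -log10 of the unadjusted p (vertical axis) for each gene tested, with genes past an adjusted p of 0.05 in blue (higher in males) or red (higher in females). The 6 genes with a log2 fold change beyond 6, which are Xist and 5 Y-linked genes, lie outside the axis, and Ucp1 at -5.16 is the lowest point drawn.

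Y-linked transcripts were found in the male libraries and were nearly or fully missing from the female ones, and Xist showed the opposite. Kdm5d, a histone H3K4 demethylase gene (chromosome Y, 897788 to 956786), was at 19.4 ± 1.33 CPM in males and had 0 counts in females, at least 905-fold higher against a floor of 3 counts over the female group. Uty, the Y-linked relative of Kdm6a, was at 15.3 ± 0.435 CPM in males with 0 counts in females, at least 710-fold higher. Ddx3y, an RNA helicase gene, reached 54.3 ± 3.78 CPM in males against 3 counts over the 4 female libraries, a ratio of 2530 (95% counting interval 865 to 12300). Eif2s3y, which encodes a translation initiation factor subunit, reached 42.1 ± 2.32 CPM against 8 female counts, a ratio of 735 (373 to 1700). These 4 of the 9 fixed Y-linked genes were tested and all were called (4 adjusted over the list alone). Zfy1, Zfy2, Sry, Usp9y and Uba1y had at most 2 counts over a sex and were not tested. The further genes tested that are annotated on the Y chromosome were Gm29650 and Gm47283. Gm29650 was at 0.949 ± 0.0836 CPM in males with 0 counts in females. Gm47283 was at 14.4 ± 8.17 CPM in females and 7.35 ± 0.394 in males (adjusted p = 0.13). Both are named outside the fixed rule, after their values were seen. The origin of the Gm47283 reads is uncertain, since females carry no Y chromosome. Whether the X chromosome carries the same sequence was not examined. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460375 to 103483217), was at 192 ± 11.6 CPM in females and 0.277 ± 0.0669 in males, a ratio of 693 (521 to 943) over 47 male counts. The intervals cover counting error only, and the labels of all 8 libraries matched these genes.

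On the X chromosome, some of the genes known to escape inactivation were higher in females. Of the 15 listed escape genes tested, 6 were higher in females, 0 were higher in males and 9 were not called (10 and 1 adjusted over the list alone). Kdm6a, a histone H3K27 demethylase gene, was at 29.1 ± 1.44 CPM in females and 15.3 ± 0.313 in males (log2 fold change -0.93, SE 0.05, adjusted p = 1.1e-06). Kdm5c (-0.69, adjusted p = 7.7e-06), Ddx3x (-0.67, adjusted p = 3e-05) and Eif2s3x (-0.69, adjusted p = 3.9e-05) are the X-linked counterparts of 3 of the Y genes above and were each about 1.6-fold higher in females. Pbdc1 (-0.51, adjusted p = 0.011) and Car5b, a mitochondrial carbonic anhydrase gene (-1.31, adjusted p = 0.011), completed the 6. Among the other members, Shroom4 (0.13) and Tmsb4x (0.28) had positive log2 fold changes. Those of 1810030O07Rik (-0.14), Utp14a (-0.07), Bgn (-0.22), Jpx (-0.35), Ftx (-0.11), 5530601H04Rik (-0.38) and Mid1 (-0.49) were negative. The adjusted p of these 9 genes lay between 0.08 and 0.68, and that of Bgn passed the threshold without female replicate 2 (0.04).

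Of all 22 X-linked genes called, 17 were higher in females and 5 in males. The 17 include Xist and the 6 escape genes above, so the comparison with autosomes below rests partly on them. The share without them was not computed, so an excess among the other X-linked genes is not shown. The share of genes higher in females was 3.35% on the X and 1.7% on autosomes (odds ratio 2, 95% interval 1.14 to 3.3, two-sided Fisher's exact test across genes, p = 0.0094; genes are not independent replicates). Outside the escape list, Maged2 (30.2 ± 0.579 CPM in females, 24.5 ± 0.75 in males, log2 fold change -0.3), the membrane protein gene Itm2a (-0.34) and the basement membrane collagen gene Col4a6 (-0.68) were higher in females. Amot, whose protein angiomotin acts at cell junctions (0.49), and Igsf1 (0.45) were higher in males, with adjusted p from 0.0024 to 0.021 over these 5 genes. The calls of Itm2a, Col4a6 and Igsf1 were lost in some fits with 1 library left out, with highest adjusted p of 0.055, 0.06 and 0.051 without female replicates 1, 2 and 3. Without female replicate 3, 13 X-linked genes were called.

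Among autosomal genes, the largest increases in males included a complement gene, an interferon-inducible gene and a steroid-responsive gene. C7, a terminal complement component (chromosome 15, 4988762 to 5063773), was 4.09-fold higher in males (2.88 ± 0.786 CPM in females, 11.8 ± 2.54 in males, adjusted p = 0.00028). Ifi205, of an interferon-inducible family whose near-identical copies make its counts uncertain, was 3.7-fold higher (adjusted p = 1e-05). Fkbp5, a co-chaperone of steroid receptors whose transcription rises with glucocorticoids and androgens, was at 16.9 ± 4.57 CPM in females and 58.9 ± 10.8 in males, 3.48-fold higher (adjusted p = 3e-04). The methyltransferase gene Inmt (2.35-fold), the acyl-CoA synthetase gene Acsm5 (2.2-fold), the carboxypeptidase-like gene Cpxm2 (2.08-fold) and the transcriptional coactivator gene Eya2 (2.07-fold) were also higher in males. The liver transcript Alb, named outside the rule after its values were seen, was also higher in males (19.2 ± 1.67 CPM in females, 32 ± 3.28 in males). Pgf, a growth factor of the VEGF family (1.95-fold), Fam107a (1.94-fold), the guanine nucleotide exchange factor gene Mcf2l (1.9-fold) and Txnip, a thioredoxin inhibitor that limits glucose uptake (1.88-fold, 374 ± 37.9 CPM in females and 704 ± 88.4 in males) were among the 12 largest increases of genes of at least 1 in mean log2 CPM. The call of Fam107a (adjusted p = 0.048) held in 1 of 8 fits with a library left out, with 0.11 without female replicate 2. It was lost in DESeq2 (adjusted p = 0.051), and its adjusted p ran from 0.0009 to 0.51 over the alternatives.

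The largest autosomal increases in females were led by adipocyte genes. Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), was at 40 ± 32.8 CPM in females and 1.17 ± 1.65 in males (log2 fold change -5.16, SE 0.83, adjusted p = 0.0077), with a wide spread in both sexes. It missed the threshold in limma-voom (adjusted p = 0.12), and its adjusted p ran from 4.6e-07 to 0.98 over the alternatives. The lipid droplet coat gene Plin1 was 5.71-fold higher in females (15.6 ± 5.93 CPM against 2.72 ± 1.36, adjusted p = 0.0022). Pck1, of glyceroneogenesis and gluconeogenesis (5.37-fold), the adipokine genes Adipoq (5.33-fold) and Retn (4.52-fold), and Cfd, which encodes the complement protease adipsin (3.58-fold), were higher in females. So were the desaturase gene Scd1 (5.04-fold, 151 ± 60.2 CPM against 29.9 ± 7.56), the lipid droplet gene Cidec (4.78-fold), the carbonic anhydrase gene Car3 (4.77-fold), the cysteine dioxygenase gene Cdo1 (4.29-fold), the fatty acid elongase gene Elovl6 (3.45-fold) and the protein kinase A subunit gene Prkar2b (3.29-fold). Adjusted p for these 12 genes lay between 0.00097 and 0.013, and each call held in all 8 fits with a library left out.

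**Figure D2:**
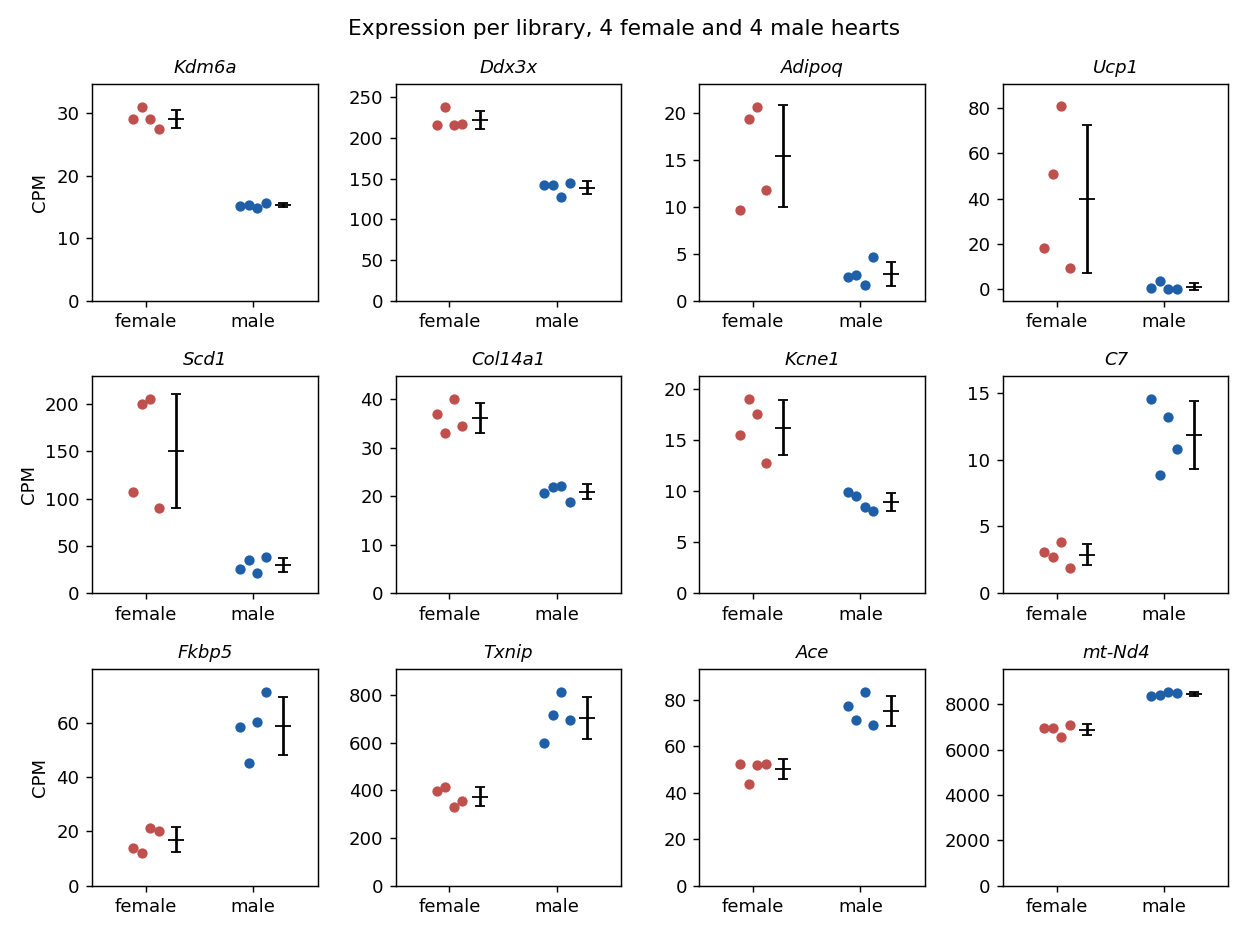
CPM of 12 genes (vertical axes, each with its own scale) in each female (red) and male (blue) library, with the mean and SD of the 4 libraries as a bar beside the points. The male and female values did not overlap in any of these genes, and the female values of Ucp1, Adipoq and Scd1 spread more widely than those of Kdm6a or Ddx3x.

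Of the 3 fixed lists on fat and lipid storage, camera called that of white adipocyte markers. Pairs of counts in parentheses follow the order of the sexes in their sentence. Of 12 white adipocyte markers tested, 10 were higher in females, 0 were higher in males and 2 were not called (10 and 0 adjusted over the list alone). The median log2 fold change was -2.26 (camera with a preset correlation of 0.01, adjusted p = 3.3e-12; adjusted p = 0.5 with an estimated correlation). Adrb3, the adipocyte beta-adrenergic receptor gene, was 9.79-fold higher in females (3.15 ± 1.05 CPM against 0.321 ± 0.2), and Retn is given above. The 2 members not called, Lipe and Nnat, had log2 fold changes of -0.18 and -0.19. The mean log2 CPM of the list was 3.12 to 3.83 in the female libraries and 1.05 to 2.24 in the male ones. Of 9 brown adipocyte markers, 4 were higher in females and 2 in males (5 and 2 adjusted over the list alone; median -1.02, camera adjusted p = 0.1). Ucp1 and the thyroid hormone deiodinase gene Dio2 (2.24-fold, adjusted p = 0.0034) were among the 4. The 2 higher in males, Cox8b (0.15, adjusted p = 0.04) and Cox7a1 (0.2, adjusted p = 0.048), encode cytochrome oxidase subunits that heart muscle also expresses. Each held its call in 1 of 8 fits with a library left out, with 0.11 and 0.13 without male replicate 3. Of 21 lipid droplet and lipogenesis genes, 6 were higher in females and 1 in males (8 and 3 adjusted over the list alone; median -0.02, mean -0.33, camera adjusted p = 0.1). Scd1 and the fatty acid synthase gene Fasn (2.77-fold, adjusted p = 0.0014) were higher in females and Dgat2, of triglyceride synthesis, in males (0.16, adjusted p = 0.049, held in 1 of 8 fits with a library left out and 0.13 without female replicate 4). The call of the lipogenesis list appeared without female replicate 4 (adjusted p = 0.023) and without male replicate 4 (0.035), and that of the brown adipocyte list without female replicate 4 (0.032).

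Mitochondrially encoded transcripts were higher in males. Of 13 mitochondrially encoded protein genes, 9 were higher in males and 0 in females (12 and 0 adjusted over the list alone), with a median log2 fold change of 0.28 (camera adjusted p = 8.7e-11; adjusted p = 0.5 with an estimated correlation). The complex I gene mt-Nd4 was at 6880 ± 235 CPM in females and 8460 ± 83.6 in males (0.3, SE 0.03, adjusted p = 0.00075), and the cytochrome b gene mt-Cytb at 21400 ± 1060 and 25300 ± 295 (0.25, SE 0.04, adjusted p = 0.005). Mitochondrial genes held 10.74% ± 0.62 of counts in females and 12.25% ± 0.2 in males (exact two-sided permutation test, p = 0.029, the smallest that 4 against 4 allows). The mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd3 and mt-Nd4l values, 2.6 to 14.9 CPM beside 44700 ± 2370 in females for mt-Co1, are uncertain, because a near-identical nuclear copy of this stretch exists; 4 of the 9 calls are among them. Of 31 nuclear-encoded respiratory chain genes, all had a positive fold change and 0 were called (2 and 0 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 3.4e-06; adjusted p = 0.68 with an estimated correlation). The member with the smallest p was Cox4i1, a cytochrome oxidase subunit gene (0.13, adjusted p = 0.066 by edgeR, 0.0032 by DESeq2, 0.046 by limma-voom and up to 0.97 over the alternatives). Of 27 fatty acid oxidation genes, 1 was higher in males (10 and 0 adjusted over the list alone; median 0.09, camera adjusted p = 5.7e-06; adjusted p = 0.68 with an estimated correlation). This gene, the short-chain acyl-CoA dehydrogenase gene Acads (0.19, adjusted p = 0.029), lost its call in 5 of the fits with a library left out, with a highest adjusted p of 0.09 without male replicate 3.

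Glycolysis and cholesterol genes gave few single calls. Of 21 glucose uptake and glycolysis genes, 2 were higher in males and 1 in females (3 and 1 adjusted over the list alone; camera adjusted p = 0.52). Ldhb, a lactate dehydrogenase subunit gene (0.15, adjusted p = 0.042), and Pfkfb1 (0.25, adjusted p = 0.046) were higher in males, and the enolase gene Eno1 in females (-0.2, adjusted p = 0.023). With a library left out, the call of Pfkfb1 was lost in all 8 fits and those of Ldhb and Eno1 held in 1 and 4. The highest adjusted p were 0.12 for Pfkfb1 and 0.11 for Ldhb, without male replicate 3, and 0.065 for Eno1, without female replicate 1. Of 21 cholesterol synthesis genes, 1 was higher in females and 20 were not called (1 adjusted over the list alone). The list's median was -0.1 (camera adjusted p = 0.00057; adjusted p = 0.22 with an estimated correlation).

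Several extracellular matrix genes were lower in males. Of 28 matrix genes, 8 were higher in females and 1 in males (14 and 1 adjusted over the list alone), with a median log2 fold change of -0.16 (camera adjusted p = 3.4e-06; adjusted p = 0.68 with an estimated correlation). The fibril-associated collagen gene Col14a1 was at 36.2 ± 3.07 CPM in females and 20.9 ± 1.57 in males (-0.79, SE 0.07, adjusted p = 0.00014), and lumican, Lum, at 70.8 ± 3.18 and 44.7 ± 4.35 (-0.66, SE 0.06, adjusted p = 0.00028). The metalloproteinase inhibitor gene Timp3 was higher in males (0.32, adjusted p = 0.03, held in 3 of 8 fits with a library left out and 0.089 without male replicate 3). Of 15 fibroblast markers, 2 were higher in females and 1 in males (11 and 1 adjusted over the list alone; median -0.16, camera adjusted p = 1.7e-05; adjusted p = 0.63 with an estimated correlation). Smoc2, a matricellular protein gene (114 ± 3.84 CPM in females, 85.3 ± 1.69 in males, -0.41, adjusted p = 0.00014), and Lum were higher in females. Dpep1, a membrane dipeptidase gene, was higher in males (40.1 ± 3.52 CPM in females, 70.3 ± 7.51 in males, 0.81, adjusted p = 3e-04).

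Among genes of contraction, conduction and cardiac signalling, the sexes differed in single members, and no such list was called by camera. The libraries are of whole tissue, so the cells that made these transcripts are not known. Of 24 genes of the cardiac action potential, 3 were higher in females (3 in females and 4 in males adjusted over the list alone; camera adjusted p = 0.74). Kcne1, the accessory subunit of the slow delayed rectifier potassium channel, was at 16.2 ± 2.71 CPM in females and 8.96 ± 0.89 in males (-0.86, SE 0.12, adjusted p = 0.0025), and the connexin 43 gene Gja1 at 382 ± 26.4 and 319 ± 4.23 (-0.26, adjusted p = 0.013). Of 17 genes of beta-adrenergic and renin-angiotensin signalling, 1 was higher in males and 2 in females (3 and 2 adjusted over the list alone; median -0.05, mean 0.02, camera direction down, adjusted p = 0.68). Ace, the angiotensin-converting enzyme gene, was 1.5-fold higher in males (50.1 ± 4.36 CPM in females, 75.3 ± 6.42 in males, adjusted p = 0.0012). The beta-1 adrenergic receptor gene Adrb1 (-0.32, adjusted p = 0.012) and the phosphodiesterase gene Pde3a (-0.25, adjusted p = 0.021, and 0.061 without female replicate 2) were higher in females. Of 22 sarcomere genes, 3 were higher in males (4 adjusted over the list alone; camera adjusted p = 0.3). Among them were titin-cap, Tcap (0.31, adjusted p = 0.021), and Myoz2 (0.17, adjusted p = 0.021), whose adjusted p reached 0.061 without female replicate 4 and 0.073 without male replicate 3. Of 15 hypertrophy and wall stress genes, 2 were higher in males (4 in males and 3 in females adjusted over the list alone; camera adjusted p = 0.27). They were Ankrd1, a stretch-responsive repeat protein gene (518 ± 55.3 CPM in females, 758 ± 84.4 in males, 0.55, adjusted p = 0.0074), and the skeletal alpha-actin gene Acta1 (0.69, adjusted p = 0.028, held in 3 of 8 fits with a library left out and 0.076 without male replicate 3). Acta1 and the titin-binding protein gene Myot (0.52, adjusted p = 0.013) were the 2 of 10 skeletal muscle markers higher in males (4 and 1 adjusted over the list alone; camera adjusted p = 0.1, and 0.045 without male replicate 4). Of 20 calcium handling genes, 0 were called by edgeR (1 in each direction adjusted over the list alone; camera adjusted p = 0.76). The smallest p was that of the calcium channel subunit gene Cacna2d1 (0.16, adjusted p = 0.065 by edgeR, 0.012 by DESeq2 and up to 0.67 over the alternatives).

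Chamber markers separated 1 library from the rest. Of 14 atrial cardiomyocyte markers, 1 was higher in females (1 adjusted over the list alone; median -0.29, camera adjusted p = 0.077). This was the cardiac transcription factor gene Tbx5 (44.9 ± 2.39 CPM in females, 33.7 ± 4.53 in males, -0.42, adjusted p = 0.02), with adjusted p of 0.058 without female replicate 2, 0.054 without male replicate 3 and 0.01 without male replicate 4. The list's mean log2 CPM was 5.04 in male replicate 4 and 6.32 to 6.5 in the other 7 libraries, and Nppa, which encodes atrial natriuretic peptide, was at 186 CPM there and between 1130 and 1340 CPM elsewhere. Without male replicate 4, the list's adjusted p was 0.35, and without male replicates 1, 2 and 3 it was 0.019, 0.047 and 0.0068. Of 10 ventricular markers, 1 was higher in females, Kcne1 (2 in females and 1 in males adjusted over the list alone; camera adjusted p = 0.38).

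**Figure D3:**
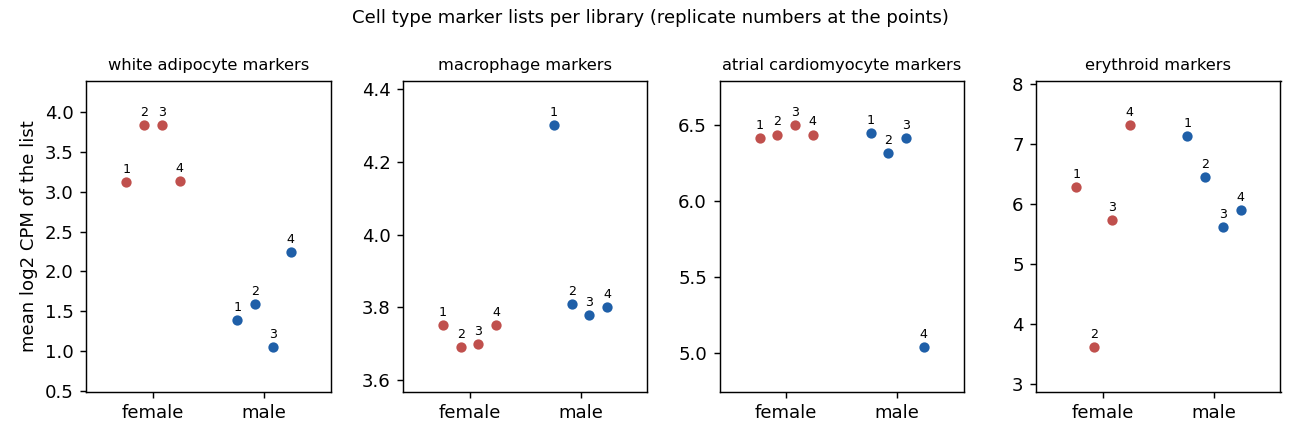
Mean log2 CPM (vertical axes) of 4 cell type marker lists in each library, with female libraries in red, male libraries in blue and replicate numbers at the points. White adipocyte markers separate the sexes (3.12 to 3.83 against 1.05 to 2.24), male replicate 1 is high in macrophage markers (4.3), male replicate 4 is low in atrial markers (5.04) and female replicate 2 is low in erythroid markers (3.61).

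Hormone-responsive and clock genes differed singly. Of 14 androgen-responsive genes, 1 was higher in males, Fkbp5, and 1 in females. The list had 2 and 1 calls adjusted over the list alone and a camera adjusted p of 0.6. Of 14 glucocorticoid-responsive genes, Fkbp5 and the kinase gene Map3k6 (0.74, adjusted p = 0.031, held in 4 of 8 fits with a library left out and 0.083 without male replicate 3) were higher in males (5 in males and 2 in females adjusted over the list alone). This list's camera adjusted p was 0.097, with 0.012 without female replicate 3 and 0.032 without female replicate 4. Of 11 estrogen-responsive genes, 1 was higher in females, the cytokine signalling inhibitor gene Cish (-0.42, adjusted p = 0.025, held in 3 of 8 fits with a library left out and 0.075 without male replicate 3), which was also the 1 adjusted over the list alone (median 0.03, mean -0.03, camera direction up, adjusted p = 0.99). Of 19 circadian clock genes, 3 were higher in males and 1 in females (6 and 4 adjusted over the list alone; camera adjusted p = 0.11, and 0.017 without male replicate 2). The clock repressor gene Nr1d1 (77.4 ± 13 CPM in females, 113 ± 6.77 in males, 0.54, adjusted p = 0.012) was higher in males and Npas2, an activator of the clock (-0.38, adjusted p = 0.027), in females. The call of Npas2 held in 2 of 8 fits with a library left out, with 0.077 without female replicate 1. Of 20 immediate early genes, 2 were higher in females (2 adjusted over the list alone), the phosphatase gene Dusp1 (101 ± 2.22 CPM against 74.3 ± 5.56, -0.44, adjusted p = 0.00095) and the AP-1 gene Fosl2 (-0.45, adjusted p = 0.0077). The list had a camera adjusted p of 0.077, with 0.0024 without female replicate 2 and 0.013 without male replicate 2. Of 16 xenobiotic and eicosanoid cytochrome P450 genes, 3 were higher in males (4 in males and 1 in females adjusted over the list alone; camera adjusted p = 0.27). Among them were the monooxygenase genes Fmo2 (0.42, adjusted p = 0.0059) and Cyp4b1 (0.32, adjusted p = 0.013).

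Heat shock genes leaned to males without any passing the test singly. All 14 had positive fold changes, 0 were called by edgeR (9 and 0 adjusted over the list alone) and the median was 0.2. Camera gave an adjusted p of 8.5e-05, and of 0.68 with an estimated correlation, and fry 1 of 0.18. The list's mean log2 CPM overlapped between the sexes, at 6.95 to 7.41 in females and 7.18 to 7.85 in males. The smallest p was that of Hsph1, an Hsp110 chaperone gene (65.9 ± 11 CPM in females, 97.1 ± 19.9 in males, 0.56, adjusted p = 0.05). It passed the threshold without female replicate 3 (0.038) and without male replicate 4 (0.024), and its adjusted p ran from 0.00072 to 0.99 over the alternatives. Cytosolic ribosomal protein genes showed 0 calls among 30 (0 adjusted over the list alone), with Rpl38 having the smallest p (-0.1, adjusted p = 0.35; camera adjusted p = 0.39). Cell cycle genes showed 0 calls among 24 (0 adjusted over the list alone; median -0.03, mean 0.03, camera direction up, adjusted p = 0.99), with the smallest p for Cenpf, a centromere protein gene (-0.45, adjusted p = 0.17, and 0.037 without male replicate 4).

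The fixed lists of immune cells and pathways held few called genes. Of 15 macrophage markers, 2 were higher in males, the scavenger receptor gene Cd163 (20.5 ± 2.91 CPM in females, 26.2 ± 1.24 in males, 0.35, adjusted p = 0.044) and the efferocytosis receptor gene Mertk (0.34, adjusted p = 0.049). The list had 4 and 0 calls adjusted over the list alone and a median of 0.23 (camera adjusted p = 0.008; adjusted p = 0.68 with an estimated correlation). The macrophage list's mean log2 CPM was 4.3 in male replicate 1 and at most 3.81 elsewhere, and its call was lost without that library (adjusted p = 0.097). With a library left out, the calls of Cd163 and Mertk held in 1 and 2 of 8 fits, with 0.12 without female replicate 2 and 0.13 without male replicate 3. Of 14 MHC class II and antigen presentation genes, 0 were called by edgeR (0 adjusted over the list alone), with Cd74, the invariant chain gene, having the smallest p (0.49, adjusted p = 0.078, and 0.028 without male replicate 3). Their median was 0.19 (camera adjusted p = 0.039; adjusted p = 0.8 with an estimated correlation), and the call was lost in 6 of 8 fits with a library left out, with a highest adjusted p of 0.18 without male replicate 1. Of 16 complement genes, C7 and the anaphylatoxin receptor gene C5ar1 (0.52, adjusted p = 0.022, held in 4 of 8 such fits and 0.064 without female replicate 3) were higher in males and Cfd in females (2 and 1 adjusted over the list alone; camera adjusted p = 0.27). Of 23 interferon response genes, 1 was higher in females (1 adjusted over the list alone), Ifi27 (-0.42, adjusted p = 0.022, and 0.067 without male replicate 3). The list's camera adjusted p was 0.1 and ranged from 0.011 without male replicate 4 to 0.83 without male replicate 3. Of 5 neutrophil markers, 1 was higher in females, the calprotectin gene S100a9 (1.36 ± 0.51 CPM against 0.28 ± 0.138, 4.83-fold, adjusted p = 0.0063; 3 in females and 1 in males adjusted over the list alone; camera adjusted p = 0.35).

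Lymphocyte, blood and neural markers gave few calls. No gene was called by edgeR among 12 B cell, 11 T and NK cell, 7 thymocyte, 9 platelet and 9 erythroid markers. The members with the smallest p were Ebf1 (-0.11, adjusted p = 0.45), Cd4 (-0.31, adjusted p = 0.42), Cd1d1 (-0.57, adjusted p = 0.089), Gp9 (0.79, adjusted p = 0.26) and Slc4a1 (-0.27, adjusted p = 0.83). Cd1d1 passed the threshold in DESeq2 (adjusted p = 0.025) and without female replicate 1 (0.044), with up to 0.81 over the alternatives. Adjusted over the list alone, 1 thymocyte marker was higher in females and 0 markers of the other 4 lists were called. The camera adjusted p were 0.19, 0.99, 0.27, 0.1 and 0.29 in this order, and the T and NK cell list had a median of 0.02, a mean of -0.04 and camera direction down. The B cell list was called without female replicate 3 (adjusted p = 0.019) and the erythroid list without female replicate 4 (0.015). The platelet list was called without male replicate 3 (0.00062), female replicate 4 (0.014) and female replicate 3 (0.034). Of 12 Schwann cell and neuron markers, 1 was higher in females (1 adjusted over the list alone), the peripheral neurofilament gene Prph (0.786 ± 0.32 CPM against 0.185 ± 0.0573, 4.25-fold, adjusted p = 0.0092), with a median of -0.13 (camera adjusted p = 0.011; adjusted p = 0.39 with an estimated correlation).

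Vascular and epicardial lists were not called by camera. Of 15 endothelial markers, 1 was higher in males (5 and 2 adjusted over the list alone; camera adjusted p = 0.5), the receptor kinase gene Tie1 (129 ± 7.02 CPM in females, 149 ± 7.82 in males, 0.2, adjusted p = 0.045, held in 1 of 8 fits with a library left out and 0.12 without male replicate 3). Of 15 smooth muscle and pericyte markers, 2 were higher in males and 1 in females (4 and 5 adjusted over the list alone; camera adjusted p = 0.99). Higher in males were the pericyte gene Rgs5 (396 ± 4.33 CPM in females, 447 ± 11 in males, 0.18, adjusted p = 0.017, and 0.059 without male replicate 3) and vitronectin, Vtn (0.17, adjusted p = 0.043). The call of Vtn was lost in all 8 fits with a library left out, with 0.13 without male replicate 3. Higher in females was the smooth muscle actin gene Acta2 (-0.39, adjusted p = 0.032, held in 2 of 8 such fits and 0.083 without female replicate 3). None of 12 epicardial and mesothelial markers was called by edgeR (0 adjusted over the list alone; camera adjusted p = 0.49), with the retinoic acid synthesis gene Aldh1a2 having the smallest p (-0.21, adjusted p = 0.11).

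**Figure D4:**
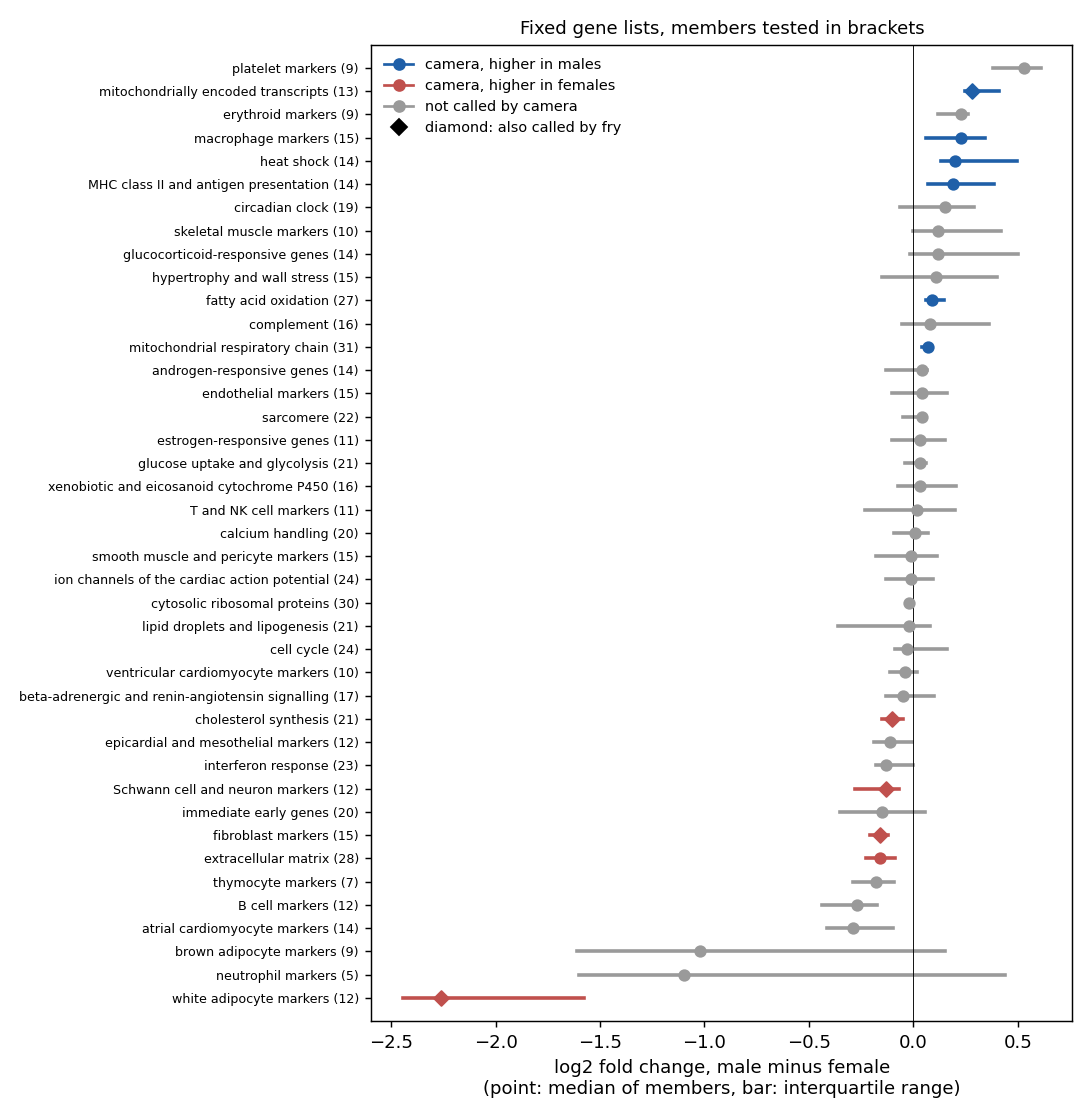
Median log2 fold change (male minus female, horizontal axis) and interquartile range of the members of each of the 41 lists tested, with lists called by camera in blue (higher in males) or red (higher in females) and diamonds for lists also called by fry. White adipocyte markers lie at -2.26, apart from the other called lists, whose medians lie between -0.16 and 0.28.

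Over all 41 lists tested, camera with the preset correlation called 11, 6 higher in males and 5 higher in females. With a correlation estimated for each list, 0 were called by camera and 4 had an unadjusted p below 0.05, while fry, which asks whether a list's genes move one way on balance, called 5. These were the white adipocyte (adjusted p = 0.016), mitochondrially encoded (0.016), fibroblast (0.036), cholesterol synthesis (0.0055) and Schwann cell and neuron (0.0078) lists. Of the 110 genes that the naming rule took, 89 were called and 59 of these were called in each of the 8 fits with a library left out.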

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

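All tests of explanations for the 3 patterns weighed here, with the list of liver transcripts, were chosen after the results they measure were seen.

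White adipocyte markers were higher in the female libraries, with a median log2 fold change of -2.26 and list means of 3.12 to 3.83 in females against 1.05 to 2.24 in males. The median was -2.27 after all libraries were thinned to equal totals. Thinning leaves the expected scaled fold change as it is, so it cannot decide what part library depth had. Fat carried with the hearts in amounts that differ between libraries may account for the pattern. Within each sex the 12 markers rose and fell together, with a mean pairwise correlation of 0.7, above the 95th percentile of 0.1 over 10000 random lists. Genes of 1 cell type or pathway can vary together for other reasons, so this cannot tell carried fat from other sources. The correlation that camera estimated for ribosomal protein genes was 0.86. For Ucp1 of brown adipocytes, 1 kind of fat in different amounts cannot be told apart from a change in Ucp1 itself or other sources. The log2 ratio of Ucp1 to Adipoq differed by -3.7 (male minus female) with an exact two-sided permutation p of 0.057. The smallest p that 4 against 4 allows is 0.029. The ratio ran from -0.33 to 1.97 in females and from -5.53 to 0.38 in males. Its lowest value, in male replicate 3, rests on 1 Ucp1 count. A sex difference in the amount or state of heart fat stays open and was not tested, and the score separates the sexes so closely (correlation -0.92) that the fit with it as a covariate, which called 6 genes, 5 of them among the 613, cannot part the explanations.

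Liver transcripts were higher in the male libraries: 26 of 26 tested had a positive log2 fold change, 14 were called higher and 0 lower by edgeR, with a median of 0.73, and Alb, the most abundant, was at 19.2 ± 1.67 CPM in females and 32 ± 3.28 in males. The median was 0.72 after thinning, which for the reason given above cannot decide what part depth had. Male-biased liver transcripts (259 and 112 counts) were 1.15 times as high relative to Alb in males as in females (95% counting interval 0.92 to 1.45). Mup20 is among them, and its near-identical copies make it uncertain. A male-to-female ratio above 1.45 lies outside this interval. Female-biased liver transcripts had 0 counts in males and 1 in females, beside 5398 and 2680 counts of Alb. Liver of the same sex carried with each heart cannot be told apart from other sources by these values. No liver was measured here, so the ratios that it would give are not known. A single liver-like source in a fixed ratio, larger in male libraries, stays open. The changes ran from 0.34 for Fgb to 1.38 for Bhmt. They were not shown to differ beyond their errors (heterogeneity test from the SE of the 26 transcripts, p = 0.19, not an exact test). These SE hold the spread between libraries that the transcripts share, so the test could miss differences. A sex difference in transcription of these genes in the heart stays open and was not tested. Of the liver transcripts, 0 are on a fixed list, and how many of them heart cells make is not known from these libraries.

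Male replicate 4 was low in atrial markers, with a list mean of 5.04 against 6.32 to 6.45 in the other males, and 13 of 14 markers were lowest there of all 8 libraries. Missing or scarce atrial tissue in the sequenced piece may account for it: the atrial median was -1.2 against the other males while that of 10 ventricular markers was -0.02. A biological difference of this heart stays open and was not tested. Without this library 434 genes, 395 autosomal genes, 19 X-linked genes and 13 lists were called.

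Named genes, list means and library measures were checked within the 4 libraries of each sex, 288 checks in all. In 23 of them 1 library stood far from the other 3, by a gap above the 95% critical value of Dixon's ratio. Chance gives about 1 in 20 checks (5%). The checks share the same libraries and some genes, so they are not independent. In CPM, female replicate 2 stood apart for Ddx3x (238 against 216 to 217), Acsm5 (3.13 against 3.76 to 3.78), Tbx5 (48.4 against 43.4 to 44.2), Ace (43.6 against 52 to 52.5) and Myot (20 against 26.2 to 27.1), the values in parentheses giving the range of the other 3 libraries. Female replicate 3 stood apart for Maged2 (31.1), and female replicate 4 for Car5b (1.4) and Tmsb4x (278). Male replicate 1 stood apart for Slc4a1 (4.66), male replicate 2 for Ifi205 (7.58) and Eya2 (1.93), and male replicate 4 for Col4a6 (2.49). Male replicate 3 stood apart for Ddx3x (127), Bgn (261), Elovl6 (0.961) and Prkar2b (1.83). Among mean log2 CPM of lists, male replicate 1 stood apart for macrophage markers (4.3), male replicate 2 for androgen-responsive genes (4.84), male replicate 3 for B cell markers (0.35) and MHC class II genes (4.58), male replicate 4 for atrial markers (5.04) and ribosomal protein genes (7.68), and female replicate 4 for T and NK cell markers (-0.22).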

How the results depend on the processing

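Thinning, removal of mitochondrial genes, the adipocyte covariate and the counts over splits, except that by fry, were chosen after the results were seen. Of 35 splits of the 8 libraries, 1, the real one, gave as many genes (613, highest other 10), autosomal genes (571, highest other 10), X-linked genes (22, highest other 0) and lists called by fry (5, highest other 1). This argues against chance for these counts, but 1 of 35 is the smallest share possible. The other splits mix the sexes, so sex differences widen the spread within their groups and lower their calls. A difference that goes with sex, such as depth, was not tested by the splits. For the 11 lists called by camera the splits do not argue against chance, since 18 of 35 gave as many, up to 20. Scaling by DESeq2 size factors or upper quartiles called 604 and 611 genes, limma-voom 615, limma on the normalized signal 600, the stricter filter 574, thinned libraries 558 and removal of mitochondrial genes 589. Asking for 1.5-fold left 182 genes, 165 autosomal and 11 X-linked, which follows from the added condition. Without a filter 859 autosomal genes and 19 lists were called, and DESeq2 called 959 genes, 904 of them autosomal; the cause was not tested. The estimated correlation left 0 lists called by camera (4 at an unadjusted p below 0.05), and fry called 5. The camera runs differed only in this setting. Against the preset 0.01, the estimates for the 11 called lists ran from -0.05 (Schwann cell and neuron) to 0.81 (MHC class II), with 0.7 for white adipocyte markers. The small p at the preset correlation are therefore not safe for lists with high estimates. With 1 library left out, the calls ranged from 315 to 490 genes, 284 to 453 autosomal genes, 13 to 19 X-linked genes and 10 to 16 lists, with fewer samples in each fit. The lowest counts came without male replicate 3 (315 and 284), and those without female replicate 2 (354 and 317) and female replicate 3 (379, 349 and 13 X-linked) also lay more than 1.5 times below the full counts. Slc4a1, not called, ran from -0.84 without male replicate 1 to 0.12 without female replicate 4. With the adipocyte covariate 6 genes were called, 5 of them among the 613, with 1 autosomal and 1 X-linked, and 7 lists, with 83.3% of the genes higher in males; the covariate nearly repeats sex, so little of the sex difference is left to test. Its log2 fold changes reversed for Utp14a (0.15), Plin1 (0.07), Pck1 (0.9), Cidec (0.82), Car3 (0.21), Cfd (0.08), Elovl6 (0.13), Prkar2b (0.28), Pde3a (0.05), Cenpf (0.75), Hsph1 (-0.05), Ankrd1 (-0.04), Acta1 (-0.06), Ifi27 (0.04) and Cd1d1 (0.39). The heat shock (camera adjusted p = 0.36), respiratory chain (0.69) and white adipocyte (0.36) lists reversed too. The covariate is the mean of the white adipocyte markers, so the loss of the sex difference of these markers follows from it. For the other genes and lists the cause was not tested. Over all alternatives, named genes kept direction and side of the threshold in 1793 fits, lost the call in 255, gained it in 22 and reversed in 16, and lists did so in 669, 29, 34 and 3. The replicate number as a block gave 427 genes, 392 autosomal, 17 X-linked and 13 lists. Deviations of same-numbered females and males correlated across genes by 0.02, -0.02, 0.05 and -0.05, and 0 females correlated best with their own number. No pairing by number was seen, but these few correlations cannot exclude a shared day or batch. Counts of the single-sample tables gave no value of their own, being identical. At the depth, spread and number of these libraries, simulated changes of 1.5-fold were recovered for 58% of 50 genes, and of 4-fold for 98%; the part of depth was not tested apart.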

Other observations

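The genes of this part were chosen after their values were seen, and no explanation was tested for them. Some genes outside the naming rule were higher in females. Lep, Otop1 and Col15a1 are members of the fixed white adipocyte, brown adipocyte and matrix lists and already counted there. The leptin gene Lep (0.503 ± 0.193 CPM in females, 0.0575 ± 0.036 in males, log2 fold change -3.04, adjusted p = 0.0053) and the leptin receptor gene Lepr (-0.83, adjusted p = 0.0012) were higher in females, as was Otop1, a proton channel gene of brown fat (-3.91, adjusted p = 0.011). The genes Fndc1 (27.2 ± 1.17 CPM in females, 18.1 ± 0.865 in males, -0.59, adjusted p = 0.00014), Col15a1 (-0.42, adjusted p = 0.00097) and Mgp, an inhibitor of calcification (-0.42, adjusted p = 0.0066), were higher in females too. So were the endothelin receptor gene Ednra (-0.34, adjusted p = 0.0019) and the interferon-inducible gene Ifi27l2a (-0.63, adjusted p = 0.0046).

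Other genes outside the rule were higher in males. The metalloproteinase inhibitor gene Timp4 was at 30.1 ± 4.32 CPM in females and 54.3 ± 7.39 in males (0.85, adjusted p = 0.0018) and the endothelial transcription factor gene Sox18 at 39 ± 3.55 and 59.7 ± 4.98 (0.61, adjusted p = 0.00097). The chemokine genes Cxcl14 (0.77, adjusted p = 0.0012) and Ccl11 (1.22, adjusted p = 0.0091), the enkephalin precursor gene Penk (0.7, adjusted p = 0.009) and Hsd11b1, whose enzyme regenerates active glucocorticoid (0.64, adjusted p = 0.0043), were also higher in males. So were the transcription factor gene Klf10 (0.63, adjusted p = 0.00072) and the Rab exchange factor gene Rin3 (0.74, adjusted p = 0.00072).

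Some libraries stood apart in genes of single cell types. Of 12203 genes considered, 58 were at least 2-fold higher in male replicate 1 than in each other library, against 0 to 2 in the other libraries. They included the leukocyte genes Cd72 (22.6 CPM against 1.85 to 2.6), Adgre1, the macrophage marker F4/80 (62.8 against 10.9 to 13.9), Acp5 (23.7 against 1.34 to 4.85) and Itgal (20 against 2.04 to 4.03). Without this library 455 genes, 418 autosomal genes, 18 X-linked genes and 11 lists were called. In female replicate 2, 7 genes were at least 2-fold lower than in each other library, among them the red cell genes Hbb-bt (42.2 CPM against 220 to 773) and Alas2 (12.3 against 62 to 218), the former of a family with near-identical copies. In male replicate 4, 31 genes were at least 2-fold lower, 7 of them on the atrial list, such as Myl7, the atrial myosin light chain gene (89.5 CPM against 380 to 493), and Bmp10 (14.1 against 115 to 135), and others outside it, such as Mybphl (11.1 against 52.7 to 61.7). Gm47283, annotated on the Y chromosome, was at 8.36, 6.36, 21.7 and 21.2 CPM in the females and between 6.84 and 7.8 in the males. The origin of its reads is uncertain, since females carry no Y chromosome and a copy on the X was not looked for.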
